A study of Arabidopsis thaliana with 9 samples.

How the data were processed

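Gene counts from roots of Arabidopsis thaliana Col-0 seedlings were analysed in 9 libraries, 3 each of mock seedlings, seedlings with 1 day on carbenicillin and seedlings with 7 days on it (10 µg/mL). Per the labels' protocols, plants grew at 24 °C with 16 h light and 8 h dark, RNA was extracted with a column kit (RNeasy), and libraries were made with a stranded total RNA kit (TruSeq). FastQC, cutadapt and edgeR were used by the authors, per the submitters' processing notes, which give no versions. The aligner, counter, genome build, annotation and strand setting are not given in the sources used here. The deposited table holds the authors' raw counts per gene, whole numbers with a different total in each library, for 28775 genes, and 2 blank lines with no gene name, which hold no values and were left out. Groups and replicate numbers came from the sample titles. Names came from the RefSeq table of assembly TAIR10.1, which had an entry for 28009 of the 28775 genes. It was used only for names, for which genes neighbour or overlap each other and for which genes are ribosomal RNA.

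The counts were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, which left 19580 genes, libraries were scaled by TMM, and all 9 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with the 3 groups as the only factor, because 3 libraries per group give few degrees of freedom. The 3 contrasts were 1 day against mock, 7 days against mock and 7 days against 1 day. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken as the absolute change divided by the square root of the F statistic. CPM values were scaled by TMM and are given as mean ± SD over 3 libraries; the sums of shoot transcripts and the floors of a count of 0 are CPM of the total counts without TMM. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 37 lists within a comparison, and again with an estimated correlation and with fry. None of the 26 list calls held with an estimated correlation, where the lowest adjusted p-values were 0.327, 0.173 and 0.999 for the 3 comparisons in the order given, or with fry, where they were 0.0618, 0.140 and 0.991. fry tests whether a list's genes move one way on balance and does not compare the list with other genes.

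The design, the lists and the alternatives were fixed before the data were examined. There were 35 lists with 654 distinct genes, all of which had an entry in the RefSeq table, and 2 lists of all plastid and all mitochondrial genes. For 556 of the 654 the listed name matched the table, and for 2 the listed name belonged to another gene there (PER1, listed as AT1G05240, and DDL, listed as AT3G08840). The fixed rule resolves such conflicts by the name; as an exception the listed identifiers were kept for these 2. The named genes were, in each comparison, the 10 largest changes in each direction among called genes with a mean CPM of at least 1 and no overlap between the groups, or else the 3 lowest p-values per direction. To these came the 4 members with the lowest p of each list that passed, and 13 genes fixed by name. Of the 31 genes called after 1 day, those outside the rule were added after their values had been seen.

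The alternatives were scaling by RLE or upper quartile, no filter or a minimum CPM of 1 in 3 libraries, DESeq2 1.42.0, a replicate block, only the 2 groups compared, organelle genes and ribosomal RNA left out, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. A pseudocount was not varied, since the values are counts. Chosen after seeing the data were a fit without the 3 libraries of low depth (mock 1, 1 day 3 and 7 days 3), a fit with depth class as a term, the leave-one-out fits of the lists and of the tests run on patterns seen in the data, and 3 short lists of light, sugar starvation and shoot genes written after the called genes and principal components had been looked at, with genes already seen among the calls left out of the light and sugar lists. Pairing by replicate number was checked from the correlation of deviations from group means. With mock, 1 of the 3 same-number pairs exceeded 0.1 for each carbenicillin group (-0.14 to 0.34 and -0.19 to 0.42), so the numbers were not treated as pairs there. Other pairs reached 0.36 (mock 1 with 1 day 3) and 0.33 (mock 1 with 7 days 3). Links with mock libraries thus exist that the numbers do not follow, and a replicate block does not remove them. Between 7 days and 1 day all 3 same-number pairs exceeded 0.1 (0.21 to 0.26, other pairs -0.20 to 0.028). The numbers therefore pair those 6 libraries by the data, though the labels do not say what they share. A fit of these 6 with the replicate block was added after seeing the data. Within groups no libraries were duplicates: chi-square per degree of freedom between counts was 9.72 to 30.8.

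The scripts were tested on simulated data, drawn for the 19580 tested genes from the real means, library sizes and each gene's own estimated dispersion. A first version had used the dispersion trend and was replaced after its result had been seen, because it gave less spread than the real genes. The simulated counts hold no shared library effects, so recovery is optimistic. For 1 day against mock 16.4% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes were recovered, with 6.34% false among the called genes. For 7 days against mock the shares were 17.9%, 50.7% and 95.5% (4.39% false), and for 7 days against 1 day 25.4%, 72.2% and 97.7% (5.42% false). All shares come from a single draw, in which the changed genes of the 2 comparisons with mock were picked separately. In the real data the median standard error was 0.166 in both, so a gap between their shares does not measure a difference in power. A simulated shift of -0.7 in the sulfate list was called by camera (adjusted p = 7.81e-14) with 0 of the 36 other lists. Genes were drawn independently, so this does not measure false list calls where the genes of a list move together. The floor of a count of 0, taken as 3 counts, covers counting error only.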

Results

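Transcripts were counted in roots of Arabidopsis thaliana seedlings of the Col-0 ecotype, in 9 libraries that formed 3 groups of 3. Carbenicillin, a beta-lactam antibiotic that blocks wall synthesis in bacteria, was in the medium at 10 µg/mL for 1 day, for 7 days or not at all. Every seedling spent 6 days on its first plate and 1 day on its second. Mock seedlings never met the antibiotic, 1 day seedlings met it on the second plate, and 7 day seedlings grew on it throughout. The series was designed to measure the response of the root transcriptome to a short and a long exposure. Mock 1 held 5820675 counts, 1 day 3 held 7533177 and 7 days 3 held 6707693, and the totals of the other 6 libraries ran from 13707967 to 16088265. The labels number the replicas without saying whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

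Depth went together with other differences between the libraries. The first principal component, with 44.8% of the variance of the 500 most variable genes, set the 3 shallow libraries apart from the other 6. The second, with 18.9%, placed all 3 mock libraries on one side and the 6 carbenicillin libraries on the other. Genes that respond to touch and early wounding, such as TCH3, ZAT12 and WRKY40, had a mean of 3.26 log2 CPM in mock 1, 3.19 in 1 day 3 and 3.74 in 7 days 3. In the other 6 libraries that mean lay between 1.59 and 2.08. Transcripts that are abundant in shoots, a set of 8 chosen after the data had been seen (CA1, CA2, LHCB1.1, LHCB1.2, RBCS2B, RBCS3B, TGG1 and LOX2), summed to 32.5 CPM in mock 1, 38.6 CPM in mock 3, 62.4 CPM in 1 day 3 and 92.6 CPM in 7 days 3. Their sum in the other 5 libraries was between 0.603 and 2.11 CPM. The mitochondrial genome took 2.199% to 5.94% of the counts and the plastid genome 1.81% to 2.41%.

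**Figure D1:**
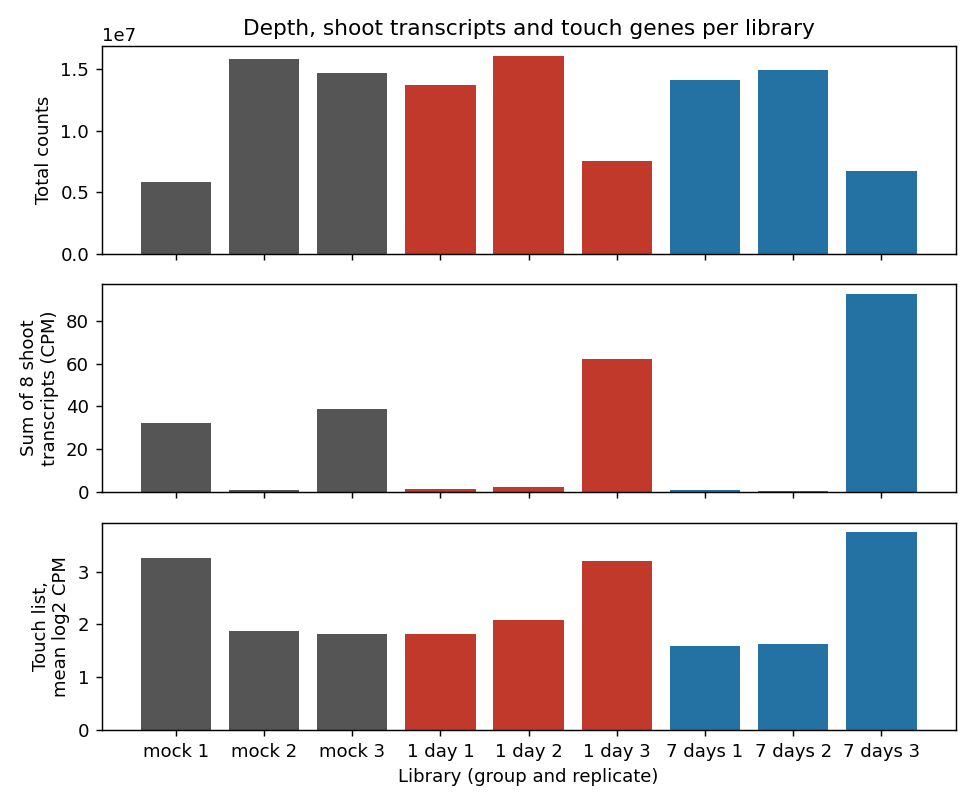
Total counts, the summed CPM of 8 shoot transcripts and the mean log2 CPM of the touch and early wounding genes, with 1 bar per library and bars coloured by group. The 3 shallow libraries (mock 1, 1 day 3 and 7 days 3) had touch means of 3.19 to 3.74, against 1.59 to 2.08 in the other 6, and shoot transcripts were also abundant in mock 3 (38.6 CPM).

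After 1 day on carbenicillin, flavonoid genes and genes of sulfate uptake and sulfur starvation lay lower than in mock roots (camera at a preset correlation, adjusted p = 0.327 for both with an estimated correlation), and 29 single genes fell while 2 rose. ELIP1, which encodes a chlorophyll-binding protein induced by strong light, went from 120 ± 37.3 CPM in mock roots to 9.52 ± 2.73 CPM (SD, n = 3 each) and fell by 3.70 on the log2 scale (SE 0.43). MYB12, an activator of flavonol synthesis, went from 34.2 ± 10.6 to 9.26 ± 1.74 CPM, a log2 fold change of -1.88 (SE 0.23). HY5, a bZIP factor central to light signalling, went from 43.5 ± 8.25 to 21.6 ± 2.66 CPM (log2 -1.01, SE 0.15), and its homolog HYH fell by 1.23. BGAL2, a beta-galactosidase, rose from 14.0 ± 4.53 to 39.2 ± 9.19 CPM (log2 1.47, SE 0.24), and the other gene that rose was AT1G74458 (log2 0.73, SE 0.12).

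Among the 29 genes that fell, UGT84A1 and UGT84A2, which glucosylate hydroxycinnamic acids, had log2 fold changes of -3.39 (SE 0.48) and -2.57 (SE 0.34). UGT78D2, a flavonoid glucosyltransferase, fell by 1.96 (SE 0.29), its neighbour AT5G17040 fell by 1.96 (SE 0.31), and the transporter DTX35 by 1.09. ELIP2, a close copy of ELIP1, had a log2 fold change of -2.78 (SE 0.34). Genes with known roles in light signalling or in the transcription of other genes had values of -1.74 (SIGE, a plastid sigma factor, SE 0.23), -1.53 (the B-box gene STH), -0.79 (TZP) and -0.60 (SPA1). CRY3, a gene of the cryptochrome family, had a value of -1.16. DDB2, which binds DNA damaged by ultraviolet light, changed by -0.96. The ABC transporters ABCI20 and ABCI21 changed by -1.63 and -1.50, and AT3G56290 and AT2G16890 by -1.85 (SE 0.24) and -1.78 (SE 0.27). PES1, DBP1, SDR1, ATK4 and GT18 also fell, with log2 fold changes between -1.04 and -0.63. The 4 remaining genes of the 29 are given with the sulfate group.

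In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these 31 of 19580 tested genes had adjusted p-values of 0.0240 (ELIP1, MYB12) to 0.0464 (AT1G74458), and 1459 genes had an unadjusted p under 0.05. Mock and 1 day libraries did not overlap in any of the 31 genes, nor in 12.3% of all tested genes, where chance gives 10% for libraries that are not linked. Deviations from group means correlated between mock 1 and 1 day 3 (0.36) and between mock 2 and 1 day 2 (0.34), so 10% is not an exact reference. The calls rested on few libraries. Leaving out mock 3, 1 day 1 or 1 day 2 left 0 genes by edgeR, with 1067, 1308 and 1144 at an unadjusted p under 0.05. The calls ended there while the changes stayed of similar size. Over 19 alternative fits, these included, log2 fold changes ran from -4.14 to -3.49 for ELIP1, from -0.64 to -0.56 for SPA1 and from 0.66 to 0.82 for AT1G74458. The numbers up and down were 4 and 8 without mock 2, 0 and 11 without 7 days 1, 5 and 15 without 1 day 3, 0 and 23 without mock 1, 8 and 36 without 7 days 2, and 5 and 32 without 7 days 3. Without the 3 shallow libraries 25 genes rose and 69 fell, 28 of the 31 among them, and DESeq2 called 59 up and 139 down, with all 31 among them. UGT84A1, SDI2, APR2, STH and SDR1 overlap an annotated gene on the opposite strand and AT1G74458, DBP1 and DTX35 one on the same strand. Their values, and those of the similar copies ELIP1 and ELIP2, UGT84A1 and UGT84A2, and UGT78D2 and AT5G17040, are uncertain as far as the counting could split or share reads.

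**Figure D2:**
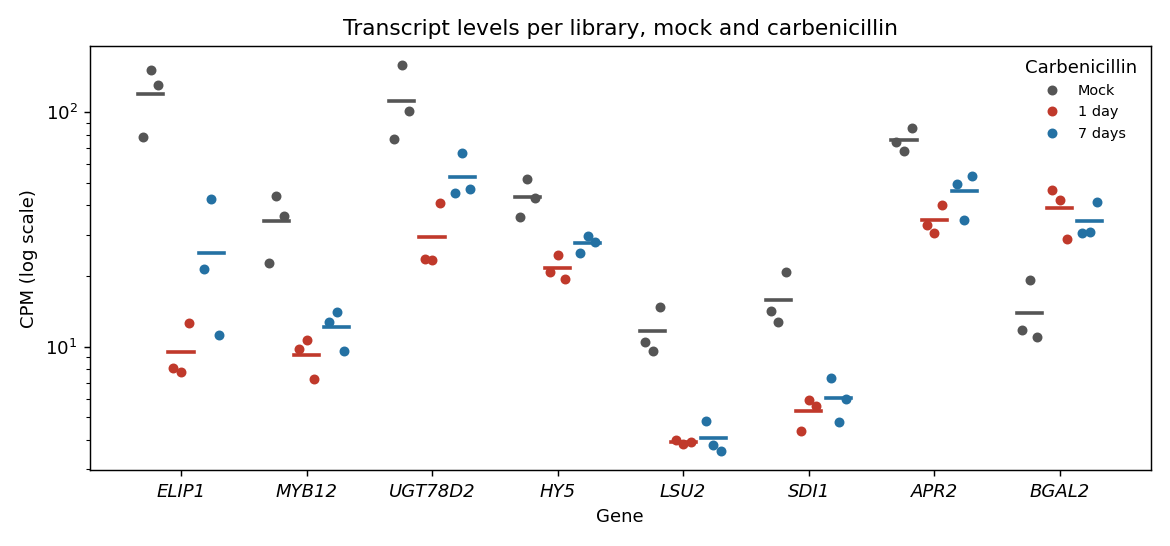
CPM on a log scale for 8 genes in each library, with points for libraries, horizontal lines for group means and colours for mock, 1 day and 7 days of carbenicillin. ELIP1 averaged 120 CPM in mock roots and 9.52 CPM after 1 day, and BGAL2 went from 14.0 to 39.2 CPM.

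The sulfate group was lower after 1 day in 15 of 15 tested members, with a median log2 fold change of -0.77 (camera adjusted p = 3.30e-11, adjusted p = 0.327 with an estimated correlation). LSU2, SDI1 and SDI2, which are induced when sulfur is short, had log2 fold changes of -1.57 (SE 0.20), -1.60 (SE 0.23) and -0.95 (SE 0.14), and APR2, which encodes adenosine phosphosulfate reductase, fell by 1.15 (SE 0.17). These 4 members passed over all genes and 9 passed when adjusted over the list alone. The flavonoid group was lower in 9 of 9 tested members, with a median of -1.21 (camera adjusted p = 7.94e-12, adjusted p = 0.327 with an estimated correlation). MYB12 and UGT78D2 passed over all genes and all 9 passed when adjusted over the list alone. The flavonol synthase FLS1 had a log2 fold change of -1.41 (SE 0.33) and the chalcone isomerase-like gene CHIL one of -1.21 (SE 0.30), with adjusted p-values of 0.159 and 0.203 over all genes. Both groups passed with any 1 of the 9 libraries left out, although the single calls of MYB12, UGT78D2, LSU2, SDI1, SDI2 and APR2 ended without mock 3, 1 day 1 or 1 day 2 (0 genes called). Over 19 alternative fits, these included, their log2 fold changes were -2.09 to -1.67, -2.46 to -1.62, -1.71 to -1.35, -1.74 to -1.34, -1.02 to -0.82 and -1.28 to -1.05 in that order.

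A further 5 of the 37 lists passed camera after 1 day, each with 0 members called by edgeR over all genes. Xenobiotic detoxification genes were lower in 16 of 21 members (adjusted p = 0.0158, adjusted p = 0.327 with an estimated correlation; 0.0967 without mock 3, 0.0954 without 1 day 3 and 0.0596 without the 3 shallow libraries). Its member with the lowest p was the glutathione transferase GSTU5 (log2 -1.04, adjusted p = 0.149), the only one that passed when adjusted over the list alone. Phenylpropanoid and lignin genes were lower in 11 of 16 (adjusted p = 0.0148, adjusted p = 0.940 with an estimated correlation; 0.119 without mock 2, 0.0742 without mock 3 and 0.0574 without 1 day 1), with PAL1 at -0.73 and CAD4 at -0.55, of which CAD4 passed when adjusted over the list alone. Cell cycle genes were lower in 31 of 35 (adjusted p = 0.00163, adjusted p = 0.940 with an estimated correlation), among them MCM5 at -0.34 and KNOLLE at -0.28 (-0.18 and -0.10 without 1 day 2), with 0 adjusted over the list alone. Without 1 day 2 the cell cycle group turned to a median of 0.04 with an adjusted p of 0.758. Evening clock genes were lower in 7 of 8, led by GI at -0.56, which passed when adjusted over the list alone (adjusted p = 0.0457, adjusted p = 0.887 with an estimated correlation). That call ended in 5 of the 9 fits without 1 library, at 0.0844 (mock 1), 0.0882 (mock 2), 0.0548 (mock 3), 0.156 (1 day 2) and 0.121 (1 day 3), and at 0.174 without the 3 shallow libraries. Its median of -0.26 became -0.27, -0.33, -0.30, -0.13, -0.22 and -0.19 in these fits, in that order. Plastid-encoded transcripts were higher in 73 of 88 members (adjusted p = 0.000572, adjusted p = 0.940 with an estimated correlation; 0.0742 without mock 3 and 0.0522 without 1 day 2), with 0 adjusted over the list alone. The other 30 lists did not pass, with medians from -0.77 (morning clock) to 0.15 (phloem) and a lowest adjusted p of 0.0836 (xylem and secondary wall).

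After 7 days on carbenicillin, the sulfate, flavonoid, endodermis and suberin, and detoxification groups lay lower than in mock roots and plastid-encoded transcripts lay higher, while no single gene passed the test. These list calls were made by camera at a preset correlation, and with an estimated correlation their adjusted p-values were 0.185, 0.425, 0.394, 0.173 and 0.567 in that order. LSU2 had the lowest p, with 4.08 ± 0.64 CPM after 7 days against 11.6 ± 2.80 CPM in mock roots (SD, n = 3 each), a log2 fold change of -1.50 (SE 0.20, adjusted p = 0.243 in edgeR's quasi-likelihood test). MYB12 followed at -1.50 (SE 0.23) and SDI1 at -1.40 (SE 0.23), both with an adjusted p of 0.395. The highest-ranked genes in the other direction were BGAL2 at 1.26 (SE 0.24), AT1G61740 at 0.85 (SE 0.16) and OXS3 at 1.01 (SE 0.20), all with an adjusted p of 0.460. edgeR called 0 of 19580 genes, with 870 at an unadjusted p under 0.05, and DESeq2 called 19 up and 28 down. Without the 3 shallow libraries edgeR called 13 genes, all lower, and with depth class as a term 2, both lower. Mock and 7 day libraries did not overlap in 9.15% of genes, where chance gives 10% for libraries that are not linked. Deviations from group means correlated between mock 2 and 7 days 2 (0.42), mock 1 and 7 days 3 (0.33), and mock 3 and 7 days 1 (0.23). The main fit did not model these links, which can make full separation rarer. The share therefore does not measure how alike these groups were. In a single draw of simulated counts without shared library effects the test recovered 50.7% of 2-fold and 95.5% of 4-fold changes for this comparison.

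The sulfate group was lower after 7 days in 12 of 15 members, with a median of -0.44 (camera adjusted p = 7.61e-11, adjusted p = 0.185 with an estimated correlation), and 6 members passed when adjusted over the list alone. LSU1, a close copy of LSU2, had a log2 fold change of -1.12 (SE 0.24) and SDI2 one of -0.84 (SE 0.14). Flavonoid genes were lower in 9 of 9 members, with a median of -0.53 (adjusted p = 2.54e-07, adjusted p = 0.425 with an estimated correlation) and 2 passing when adjusted over the list alone. Their median was -0.29 without mock 2, -1.11 without 7 days 2 and -0.27 without 7 days 3. Endodermis and suberin genes were lower in 22 of 24 members, with a median of -0.29 (adjusted p = 2.07e-08, adjusted p = 0.394 with an estimated correlation) and 1 passing when adjusted over the list alone. That group's lowest p belonged to CYP86B1, a hydroxylase of suberin synthesis (log2 -0.67, SE 0.14), followed by the transporter ABCG20 (-0.56, SE 0.18) and the acyltransferase GPAT5 (-0.51, SE 0.21; -0.32 without mock 2). Its median was -0.46 without 7 days 2. Detoxification genes were lower in 19 of 21 members (adjusted p = 6.16e-05, adjusted p = 0.173 with an estimated correlation), led by GSTU5 at -0.76 and GSTF6 at -1.72, whose reads a close copy, GSTF7 at -1.37, could share (-0.98 and -0.74 without mock 3). Plastid-encoded transcripts were higher in 80 of 88 members, with a median of 0.14 (adjusted p = 2.07e-08, adjusted p = 0.567 with an estimated correlation), and that median was 0.09 without mock 3 or without 7 days 3. All 5 groups passed in each of the 9 fits without 1 library, but plastid-encoded transcripts did not pass without the 3 shallow libraries (adjusted p = 0.111).

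Another 6 lists passed camera after 7 days, and each lost its call without at least 1 library. Mitochondrial transcripts were higher in 67 of 69 members (adjusted p = 8.51e-06, adjusted p = 0.836 with an estimated correlation; 0.828 without 7 days 2). Phenylpropanoid and lignin genes, among them CAD4 at -0.35, were lower in 14 of 16 (adjusted p = 0.00105, adjusted p = 0.567 with an estimated correlation; 0.129 without 7 days 3). Phosphate starvation genes, among them PHT1;4 at -0.37 and SPX1 at -0.98 (-0.26 without mock 2), were lower in 11 of 14 (adjusted p = 0.00351, adjusted p = 0.632 with an estimated correlation; 0.149 without mock 2 and 0.149 without 7 days 3). Antioxidant genes, among them AOX1A at -0.36 (-0.22 without mock 3), were lower in 13 of 17 (adjusted p = 0.0236, adjusted p = 0.394 with an estimated correlation; 0.0578 without mock 1, 0.0744 without mock 3, 0.0734 without 7 days 2 and 0.0694 without 7 days 3). Immunity genes were lower in 10 of 13, with 2 passing when adjusted over the list alone (adjusted p = 0.0259, adjusted p = 0.394 with an estimated correlation; 0.0706 without mock 1, 0.0505 without mock 3 and 0.196 without 7 days 2). CYP71A12, a P450 of camalexin synthesis, stood at -2.70 (SE 0.79) and PAD4 at -0.38 (SE 0.11). Genes responsive to abscisic acid and water deficit were lower in 13 of 16, among them ERD10 at -0.36 (adjusted p = 0.0320, adjusted p = 0.831 with an estimated correlation; 0.950 without mock 2, 0.702 without 7 days 1, 0.0769 without 1 day 1 and 0.0869 without 1 day 2). Antioxidant and immunity genes also missed the threshold without the 3 shallow libraries, at 0.0557 and 0.0559. Immunity was the only 1 of these 6 lists with a member that passed when adjusted over the list alone. The other 26 lists did not pass, with medians from -0.71 (morning clock) to 0.37 (aliphatic glucosinolates) and a lowest adjusted p of 0.0717 (xylem and secondary wall).

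**Figure D3:**
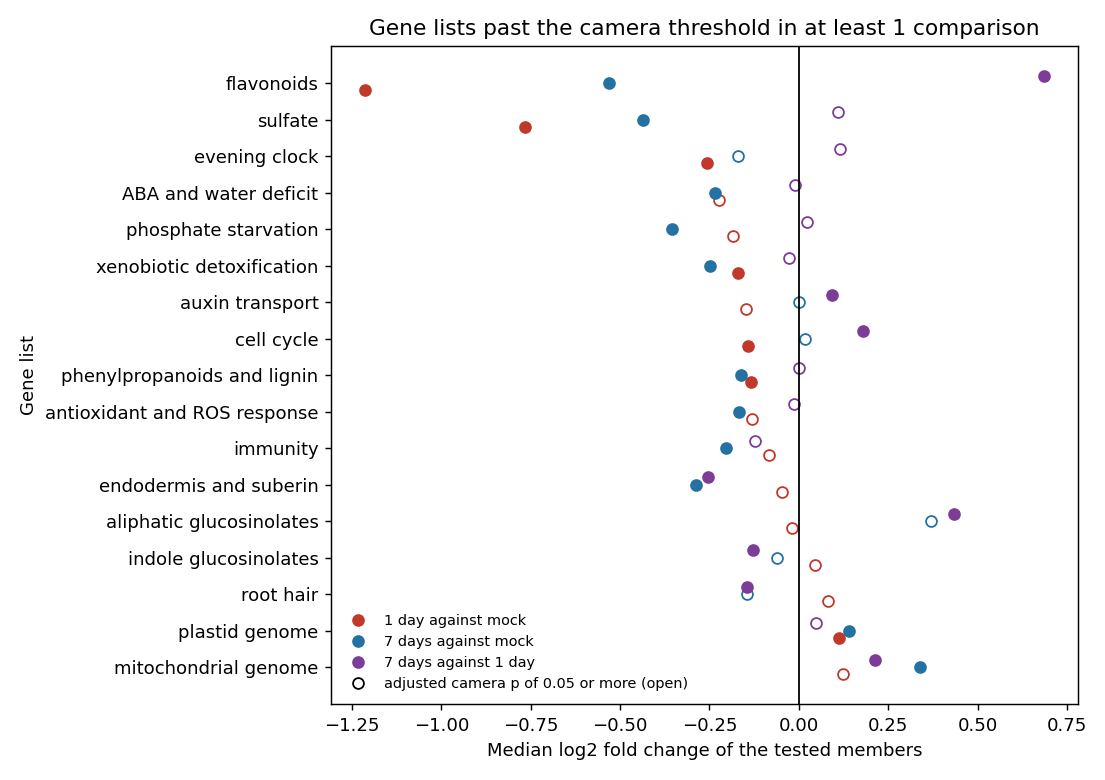
Median log2 fold change of the tested members of each list that passed camera in at least 1 comparison, with colours for the 3 comparisons. Filled points have an adjusted camera p under 0.05 and open points do not. Flavonoid genes had medians of -1.21 after 1 day and -0.53 after 7 days, and sulfate genes of -0.77 and -0.44.

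The 1 day and 7 day effects were set side by side over the 31 genes called after 1 day. All 31 kept their sign after 7 days. ELIP1, UGT84A1 and the other genes that fell had a median log2 fold change of -1.50 after 1 day and -0.85 after 7 days; they had been chosen by their 1 day change, so a smaller 7 day change can follow from that choice alone. In simulations of unchanged groups against the same mock libraries, a median of 29.5 of the 31 lowest-p genes kept their sign (27 to 31 in 50 simulations). The genes called in both comparisons numbered 0 by edgeR, with 544 sharing a direction at an unadjusted p under 0.05 in both, and 40 by DESeq2. Of those 544 genes 283 were lower and 261 higher, where the simulations gave 92.5 and 114 and independent lists would share 16.6 and 15.6. Over all tested genes, which are not independent replicates, the fold changes correlated at 0.667, against 0.507 in the simulations (0.486 to 0.531). Their covariance was 0.0507, against 0.0331 (0.0307 to 0.0365). The simulations drew each gene and each library separately, so they hold no library effects shared between genes and no link between same-number libraries. In the data, same-number libraries of the 7 day and 1 day groups correlated at 0.21 to 0.26. Such effects can raise all of these values, so the excess does not by itself show a common response. The simulated comparisons also shared their mock libraries, so that sharing alone is already in the simulated values. Part of the excess may still come from effects in the real mock libraries that many genes share, and these libraries were too few to split.

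Between 7 days and 1 day on carbenicillin, flavonoid genes lay higher after 7 days and endodermis and suberin genes lower in camera at a preset correlation (adjusted p = 0.999 for both with an estimated correlation), and no single gene passed. Endodermis and suberin genes did not pass without the 3 shallow libraries (adjusted p = 0.197). This comparison asked whether a long exposure differed from a short one at the same plant age, and it is also the test of whether the effects against mock differed. The lowest p in the upward direction belonged to ABCI20, at 82.4 ± 15.5 CPM after 7 days against 49.0 ± 7.29 CPM after 1 day (SD, n = 3 each; log2 0.75, SE 0.18), to AT4G10060 (2.49, SE 0.64) and to GT18 (0.50, SE 0.13). In the downward direction it belonged to AT5G20860 (-0.81, SE 0.17), AT1G06923 (-0.80, SE 0.19) and AT1G74458 (-0.46, SE 0.12), and these 6 genes had an adjusted p of 1.00 in edgeR's quasi-likelihood test. edgeR called 0 genes, with 398 at an unadjusted p under 0.05, and DESeq2 called 0. The 2 groups did not overlap in 6.37% of genes, where chance gives 10% for libraries that are not paired. Replicate numbers pair these libraries by the data, and pairing can make full separation rarer. The share therefore does not measure how alike the groups were. A fit with the replicate block, given below, also called no gene but had more genes at an unadjusted p under 0.05.

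Of the 37 lists, 8 passed camera between 7 days and 1 day, each with 0 members called by edgeR over all genes or adjusted over the list alone, and all 8 had an adjusted p of 0.999 with an estimated correlation. Flavonoid genes were higher after 7 days in 9 of 9 members (adjusted p = 8.41e-06), among them UGT78D2 at 0.87 (SE 0.29) and FLS1 at 0.76 (SE 0.32; 0.28 without 7 days 2), with a median of 0.68 that became 0.27 without 7 days 2 (adjusted p = 0.0438) and 1.09 without the 3 shallow libraries. Endodermis and suberin genes were lower in 21 of 24 (adjusted p = 5.80e-06), among them ABCG20 at -0.51 (-0.33 without 1 day 3, -0.21 without the 3 shallow libraries) and the Casparian strip gene CASP2 at -0.32. Their median of -0.25 became -0.15 without 7 days 3 or without 1 day 2, and the group did not pass without the 3 shallow libraries (adjusted p = 0.197). Cell cycle genes were higher in 32 of 35 (adjusted p = 3.95e-06), among them MCM5 at 0.42 (0.26 without 1 day 2) and the kinesin gene HINKEL at 0.36 (0.15 without 1 day 2, 0.56 without 1 day 1), but not without 1 day 2 (adjusted p = 0.996). Mitochondrial transcripts were higher in 65 of 69 (adjusted p = 0.000215), but not without 7 days 2 (0.679) or 1 day 3 (0.924). Aliphatic glucosinolate genes, among them SOT18 at 0.35 (0.074 without 7 days 1), were higher in 13 of 14 (adjusted p = 0.0435; 0.0588 without mock 1, 0.521 without 7 days 1 and 0.711 without 1 day 3). Root hair genes, among them EXPA18 at -0.37 (-0.22 without 7 days 3, -0.20 without 1 day 2), were lower in 20 of 26 (adjusted p = 0.0288; 0.819 without 7 days 3, 0.269 without 1 day 2, 0.0758 without 1 day 3 and 0.646 without the 3 shallow libraries). Indole glucosinolate genes, among them the myrosinase TGG4 at -0.30 (-0.17 without 1 day 3, -0.16 without the 3 shallow libraries), were lower in 19 of 25 (adjusted p = 0.0370; 0.600 without 7 days 2, 0.303 without 1 day 3 and 0.125 without the 3 shallow libraries). Auxin transport genes, among them PIN5 at 0.71 (0.35 without 7 days 1, 0.41 without 1 day 2), were higher in 13 of 16 (adjusted p = 0.0464) and passed in 2 of the 9 fits without 1 library. The values of those that ended the call were 0.0529 (mock 1), 0.0545 (mock 2), 0.0619 (mock 3), 0.189 (7 days 1), 0.0594 (7 days 3), 0.703 (1 day 2) and 0.0535 (1 day 3). The other 29 lists did not pass.

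Genes of auxin supply, root hairs, peroxide production and cell division that had been named in advance did not pass in any comparison. These 12 genes, CYP79B2, CYP79B3, GH3.3, IAA19, RSL4, EXPA7, RBOHC, RBOHD, PER71, GSTU24, CYCB1;1 and PLT2, had log2 fold changes of -0.9999 to 0.31 after 1 day (lowest adjusted p = 0.329, for RBOHC). After 7 days the range was -1.10 to 0.20 (lowest adjusted p = 0.921), and between 7 days and 1 day it was -0.11 to 0.25 (all at 1.00). RBOHC, the NADPH oxidase of root hairs, stood at 98.3 ± 2.73 CPM after 1 day against 122 ± 1.75 CPM in mock roots (SD, n = 3 each). GH3.3, at -0.9999 after 1 day, had a mock mean of 12.8 ± 16.0 CPM, and its change became 0.88 without mock 3 and -1.54 without the 3 shallow libraries. The defence marker PR1 had 0 counts in all 9 libraries, where 3 counts would be 0.186 to 0.515 CPM.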

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

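The fits of these lists without 1 library were chosen after the results had been seen; the test itself, camera on the difference between 7 days and 1 day, was fixed beforehand. That difference is also the difference between the 2 effects against mock, and 8 of the 37 lists passed it, so their effects differed between the exposure times in that test. All 8 had an adjusted p of 0.999 with an estimated correlation, and edgeR called 0 of their members.

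Cell cycle genes, such as MCM5, differed with an adjusted p of 3.95e-06, which became 0.996 without 1 day 2. Endodermis and suberin genes, such as CASP2, differed at 5.80e-06 and passed without any 1 library (0.00253 without 1 day 2, 0.00874 without 7 days 3), but stood at 0.197 without the 3 shallow libraries. Flavonoid genes, such as UGT78D2, differed at 8.41e-06, and at 0.0438 without 7 days 2. Mitochondrial transcripts differed at 0.000215, with 0.679 without 7 days 2 and 0.924 without 1 day 3. Root hair genes, such as EXPA18, differed at 0.0288, with 0.819 without 7 days 3, 0.269 without 1 day 2 and 0.0758 without 1 day 3. Indole glucosinolate genes, such as TGG4, differed at 0.0370, with 0.600 without 7 days 2 and 0.303 without 1 day 3. Aliphatic glucosinolate genes, such as SOT18, differed at 0.0435, with 0.0588 without mock 1, 0.521 without 7 days 1 and 0.711 without 1 day 3. Auxin transport genes, such as PIN5, differed at 0.0464, with 0.0529 without mock 1, 0.0545 without mock 2, 0.0619 without mock 3, 0.189 without 7 days 1, 0.0594 without 7 days 3, 0.703 without 1 day 2 and 0.0535 without 1 day 3.

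At the level of single genes the 6 libraries of the 7 day and 1 day groups can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest other split gave 0, so 10 of the 10 splits gave as many. With 0 genes in the real split every split gives at least as many, so that count decides nothing. Replicate numbers pair these libraries by the data: 4 of the 10 splits, the real one included, part all 3 pairs, and those 4 all gave 0 genes, while the other 6 part 1 pair each.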

How the results depend on the processing

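The fits without the 3 shallow libraries (mock 1, 1 day 3 and 7 days 3), with depth class as a term and with a replicate block in the 7 day and 1 day groups only, and the leave-one-out fits of the lists, were chosen after seeing the data. The numbers of genes higher and lower after 1 day, 2 and 29, were 59 and 139 by DESeq2, 12 and 49 with no filter, 8 and 50 with depth class as a term, 25 and 69 without the 3 shallow libraries, and 0 and 0 at an adjusted p under 0.01. The number higher was 7 with only the 2 groups compared (32 lower), 1 with a replicate block (40 lower, with 26 of the 31 genes shared) and 1 with an absolute log2 fold change of at least 1 (21 lower). With a replicate block and only the 7 day and 1 day groups, whose numbers pair, 0 genes passed between them (727 at an unadjusted p under 0.05) and 11 lists, with the same 8 among them. There 0 of the 50 named genes, none of which had been called, changed call or direction. In each comparison with mock, 2 of the 6 libraries correlated best with their own number. The replicate block may therefore not match the links between libraries there. Scaling by RLE gave 2 and 30, by upper quartile 2 and 26. After 7 days DESeq2 called 19 and 28, the fit without the shallow libraries 13 lower, and depth class as a term 2 lower. The overlap of the 1 day and 7 day calls was 40 by DESeq2. The stricter thresholds call fewer genes by construction, and for the other settings the cause was not tested. Lists past the threshold numbered 7, 11 and 8 in the 3 comparisons, and 0, 0 and 0 both with an estimated correlation and with fry; after 1 day 11 passed without the shallow libraries. Of 26 list results, 26 were the same with RLE or a replicate block, 22 with depth class as a term and 17 without the shallow libraries. Of 172 results for named genes, 172 were the same with RLE or no filter, 168 with upper quartile, 165 with a replicate block or only 2 groups, and 159 with DESeq2, where the other 13 passed. Without the 3 shallow libraries 156 were the same, 12 turned, 3 lost their call and 1 gained it. Of the 172, 141 had not been called in the main fit, and for these the same means no call and no turn. The 31 genes called after 1 day stayed called in 8 (PES1, SPA1) to 16 (ELIP1 and MYB12 among them) of 19 alternative fits. A pseudocount was not varied, since the values are counts. No scaling moved the median of all genes by more than 0.0245.

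Without 1 library in turn, the genes after 1 day ranged from 0 to 8 higher and from 0 to 36 lower. They were 0 and 0 without mock 3, 1 day 1 or 1 day 2, and most numerous without 7 days 2; after 7 days and between 7 days and 1 day they stayed at 0. The lists ranged from 3 (without mock 3) to 10 after 1 day, with 4 without 1 day 2, from 10 to 16 after 7 days, and from 4 (without 1 day 3) to 12 between 7 days and 1 day. Direction turned for 14 gene values outside these fits, of which none had been called, and the median of the called root hair list between 7 days and 1 day went from -0.14 to 0.0098 without the 3 shallow libraries. With a replicate block GH3.3 stood at 0.0047 between 7 days and 1 day, and with upper quartile PER71 at 0.025 after 1 day. Without the 3 shallow libraries the turned values after 1 day were CYP79B2 -0.040, GSTU24 0.025 and PER71 0.042. After 7 days they were CYCB1;1 0.20, CYP79B2 -0.13, PER71 -0.20 and RBOHD 0.071. Between 7 days and 1 day they were ABCG6 0.022, GH3.3 0.22, IAA19 -0.12, PER71 -0.24 and RSL4 0.020. The cause was not tested.

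Results that turned without 1 library had these lowest and highest values. After 1 day they were GRP7 -0.50 and 0.029, GH3.3 -1.44 and 0.88, EXPA7 -0.050 and 0.17, PER71 -0.31 and 0.32, PLT2 -0.33 and 0.018, and the cell cycle list -0.24 and 0.037. After 7 days they were CYP79B2 -0.069 and 0.16, GH3.3 -1.54 and 0.77, EXPA7 -0.15 and 0.10, RBOHD -0.20 and 0.014, PER71 -0.23 and 0.36, and CYCB1;1 -0.21 and 0.11. Between 7 days and 1 day they were BCAT4 -0.077 and 1.13, CYP83A1 -0.017 and 1.13, CYP79B2 -0.15 and 0.049, GH3.3 -0.39 and 0.071, IAA19 -0.10 and 0.40, EXPA7 -0.20 and 0.037, RBOHD -0.0072 and 0.21, PER71 -0.27 and 0.36, GSTU24 -0.16 and 0.0042, and PLT2 -0.14 and 0.21. The aliphatic glucosinolate list there had -0.062 and 0.69, the mitochondrial list -0.052 and 0.45, and the root hair list -0.28 and -0.0090, turned in camera's direction against other genes, by which all lists in this paragraph so far were counted. In camera's direction 2 more called lists did not turn but their medians did: genes of abscisic acid and water deficit after 7 days (-0.33 and 0.021; 0.021 without mock 2) and cell cycle genes between 7 days and 1 day (-0.0083 and 0.29; -0.0083 without 1 day 2). The cause was not tested. What depth alone limits was not tested: at the real depth, spread and number of libraries 16.4% of 1.5-fold and 80.6% of 2-fold changes after 1 day were recovered in simulated counts.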

Other observations

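Chosen after the results they measure had been seen were the tests of shoot RNA, of the sulfur genes, of depth and of handling, and every fit without some of the libraries. The light, sugar starvation and shoot lists were written after the called genes and principal components had been looked at, and the predictions for the light and sugar lists before their own members were tested.

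Genes induced when sugar is short were higher in roots on carbenicillin than in mock roots. Of the 11 tested members of a sugar starvation list, 10 had a positive log2 fold change after 1 day (median 0.60) and 10 after 7 days (median 0.54), and edgeR called 0 of them. DIN10, a dark-inducible gene, stood at 1.15 (SE 0.32) after 1 day and 1.34 (SE 0.33) after 7 days, and GDH1, a glutamate dehydrogenase gene, at 0.83 (SE 0.18) and 0.56 (SE 0.18). The trehalose phosphate synthase-like gene TPS8 stood at 0.78 and 0.80 (SE 0.26 each), and DIN2 was the exception at -0.33 and -0.43. Camera gave unadjusted p-values of 1.53e-08 after 1 day (0.0441 with an estimated correlation) and 5.44e-10 after 7 days (0.0318), and 0.463 for the difference between 7 days and 1 day. That difference rested on few libraries: its p was 0.00361 without 7 days 3 (median -0.21), 0.0203 without 1 day 3 (-0.14) and 4.44e-05 without the 3 shallow libraries (-0.39, 0 of 11 positive; 0.157 with an estimated correlation). The group passed with any 1 library left out at the preset correlation, but its median after 7 days was 0.28 without the 3 shallow libraries. With an estimated correlation the 1 day p was 0.0933 without mock 1, 0.0917 without mock 3, 0.0585 without 7 days 1, 0.0843 without 1 day 1, 0.0755 without 1 day 2 and 0.0869 without the 3 shallow libraries. For 7 days that p was 0.104 without mock 1, 0.0694 without mock 3, 0.0771 without 7 days 3 and 0.194 without the 3 shallow libraries. A lower sugar supply to roots on carbenicillin is a candidate explanation, but sugar supply was not measured. The gene pattern was found and tested on the same libraries. A difference in light or harvest hour between the groups, raised below for the light-regulated genes, was not tested for this list and is not excluded.

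Further light and ultraviolet genes, of which 9 were tested, were lower in 7 of 9 after 1 day (median -0.73) and in 7 of 9 after 7 days (median -0.48), and edgeR called 0 of them. RUP1, a repressor of ultraviolet-B signalling, stood at -0.81 and -0.74, the photolyase gene UVR2 at -0.94 and -0.38, and the B-box gene BBX24 at -0.75 and -0.48, while FHY1 stood at 0.43 and 0.25. Camera gave unadjusted p-values of 4.89e-06 after 1 day and 2.26e-05 after 7 days, which passed without any 1 library. With an estimated correlation the 1 day p was 0.0282, and 0.0546 without mock 3, 0.0620 without 1 day 1, 0.0937 without 1 day 3 and 0.0591 without the 3 shallow libraries. The 7 day p was then 0.0372, and 0.0841 without mock 2, 0.0618 without mock 3, 0.0812 without 7 days 1, 0.0707 without 7 days 2, 0.0675 without 7 days 3, 0.0585 without 1 day 3 and 0.0510 without the 3 shallow libraries. Between 7 days and 1 day 6 of 9 were higher (p = 0.0407, 0.245 with an estimated correlation), but p was 0.129 without 7 days 2, 0.0856 without 7 days 3, 0.335 without 1 day 1, 0.242 without 1 day 3 and 0.324 without the 3 shallow libraries.

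Light-regulated genes such as ELIP1, HY5 and MYB12 were among the 29 genes that fell after 1 day, whose median log2 fold change was -1.50. The 9 further light and ultraviolet genes gave a camera p of 4.89e-06, with the limits above. Against a different harvest hour as the whole cause, the median of the 29 stayed at -1.30 with the morning clock genes CCA1, LHY and RVE8 as a covariate, and 17 were still called (why 12 calls ended was not tested); against shoot RNA, it was -1.51 with the shoot transcripts as a covariate, and 28 were still called. That covariate removes only what follows these clock genes in a straight line, so a part of harvest hour in the fall stays open. The morning clock list had medians of -0.77 after 1 day and -0.71 after 7 days and passed in neither comparison. Both were the lowest medians among the lists that did not pass. The evening clock list, with a median of -0.26, did pass camera after 1 day at the preset correlation. Its adjusted p was 0.887 with an estimated correlation, and its call held in 4 of the 9 fits without 1 library. The further light genes were picked after the calls in the same libraries had been seen. A response of roots to less perceived light may account for the pattern. Whether it came from carbenicillin or from unrecorded differences in light or plate position was not tested.

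Sulfur-responsive genes were lower after both exposures, with LSU2, SDI1, SDI2 and APR2 at a median log2 fold change of -1.36 after 1 day. Without the 3 shallow libraries that median was -1.45 and 4 of the 4 genes were still called, so the fall did not rest on those libraries. Each group held 1 of them and the 4 genes had been chosen from the calls, so this was no independent test of low depth as the cause. A part in the same response as the light-regulated genes cannot be told apart from a separate one: the 7 day change was 84.1% of the 1 day change in these 4 genes and 59.3% in the other 25 that fell (exact permutation p = 0.000379 over 23751 arrangements of genes, which are not independent), but 76.3% and 66.3% without 7 days 2 (permutation p = 0.134).

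Shoot transcripts stood out in 4 libraries, with CA1, a carbonic anhydrase of leaves, at 6.01 CPM in mock 1, 5.70 in mock 3, 5.31 in 1 day 3 and 11.9 in 7 days 3, and at most 0.0730 CPM in the other 5. Low sequencing depth does not account for all of them, since 1 of the 4, mock 3, was a deep library. Touch and early wounding genes were higher in the 3 shallow libraries by 1.60 on the log2 scale (exact permutation p = 0.0370, the smallest that 27 arrangements within groups can give), which restates a difference already seen. That list stood at 1.81 log2 CPM in mock 3, no higher than in mock 2 (1.87), so rougher handling cannot be told apart from other sources of shoot RNA. No biological explanation was tested, since each of the 3 groups held at least 1 such library.

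For the numbers of single genes, the 6 libraries of a comparison with mock can be split 3 against 3 in 10 ways, too few for a share under 0.05. After 1 day the real split gave 31 genes and the highest other 0, so 1 of the 10 gave as many. After 7 days the real split gave 0 genes and the highest other 0, and 10 of the 10 gave as many. With 0 genes in the real split every split gives at least as many, so that count decides nothing.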
